A study of Mus musculus with 12 samples.

How the data were processed

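RNA-seq was made from mouse embryonic stem cells in 12 libraries, with 4 libraries each of wild type in 2i, Tfcp2l1 knockout in 2i and wild type in FBS. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a TruSeq kit. Per the submitters' processing notes, CASAVA 1.8.2 and Cufflinks (version not given) were used with the mouse build mm9; the aligner was not given in the sources used here. The authors deposited 1 table of FPKM values per RefSeq transcript, with a lower and an upper bound and a status for each, per the file headers. FPKM are normalized to transcript length and library size, so the read depth cannot be recovered, and a count test was not used. The FPKM summed to 347772 to 358340 per library. The authors' bounds give the precision: for transcripts of 5 to 20 FPKM the median distance to a bound was 8.32% to 10.0% of the value. In 1637 to 2186 transcripts per library the upper bound lay below the FPKM value itself, so the bounds were used only for that description.

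The table held 30761 transcripts' entries. Gene names came from RefSeq (GRCm38.p6) and GENCODE vM21 name tables, which gave a symbol to 98.8% of entries; 362 had none. Coordinates are those of the deposited table, on mm9, printed 1-based. Entries of a symbol were summed, giving 23503 genes. Of the entries, 23 had a failed estimate in some library and were listed at 0; the 5 genes they touched (Acp1, Hnrnpd, Nolc1, Ralgds and Ss18) were left out. No mm9 genome or annotation was used here, so exons were not measured separately. Genes with near-identical copies share reads, and the way Cufflinks divided them was not given.

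Groups came from the labels. Genes with at least 1 FPKM in at least 4 libraries were tested, 12329 in all, on log2(FPKM + 1). A limma model with 1 mean per group was fitted to all 12 libraries, with eBayes and an intensity trend, and genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were called, as knockout minus wild type in 2i and as 2i minus FBS in wild type. Adjusted p-values of genes are from limma throughout. Nothing in the labels says that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Tfcp2l1 was also tested with an exact two-sided permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

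The comparisons, tests, 24 gene lists, cell type markers and the rule for naming genes were fixed before the data were examined. The lists covered naive and general pluripotency, formative and primed epiblast, endoderm, streak and mesoderm, neuroectoderm, trophoblast, 2-cell-like, germline and imprinted genes; targets of LIF and STAT3, Wnt, ERK, BMP and Nodal, and p53; and DNA methylation, glycolysis, cholesterol synthesis, actin and serum response, stress responses, lysosome and autophagy, cell cycle, oxidative phosphorylation and junctions. Lists were tested with limma's camera with a preset correlation of 0.01, two-sided and adjusted over the 24 lists. With an estimated correlation 0 of 24 lists passed in either comparison; at an unadjusted p under 0.05 there were 2 in each, fry gave 17 and 22, and rank-based camera 12 and 11. Marker lists were fibroblasts, parietal and visceral endoderm, and epiblast-like, trophoblast-like and neural-like cells, adjusted among themselves; of a further list of 8 genes, Y-linked ones and Xist, none passed the filter, so it was not tested. Genes were named by rule: Tfcp2l1; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, with at least 2 FPKM in the higher group, 1 per gene family and no unnamed models; up to 4 members per list with the smallest adjusted p; and a list's highest-expressed member that did not pass. Genes named outside it are said to be so, and the results of some single genes are not reported here.

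The model was tested on simulated data in which 200 of 12329 genes were changed, in 10 simulations. For the knockout comparison 88.5%, 96.9% and 97.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 5.63% of calls false; for 2i against FBS 90.4%, 97.8% and 97.4%, with 5.79% false. A shifted list was called in 10 of 10 simulations and an unshifted list in 0 of 230 tests, in each comparison. Simulated genes varied independently, whereas members of real lists were correlated, with an estimated 0.91 among 2-cell-like genes. The 0 of 230 thus does not show how often lists are falsely called in the real data.

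Alternatives were other pseudocounts (0.1 and 0.01), no filter or a filter of 5 FPKM, median-ratio, quantile and TPM scaling, the 8 libraries of a comparison alone, the replicate number as a block, other eBayes settings, array weights, the highest entry per symbol, stricter thresholds, other list tests, and leaving out each library. Leaving out chromosome 6 genes, removing the chromosome 6 offset, and adding the mean log2 level of the fibroblast markers as a covariate were chosen after the data were seen. Effects against the shared wild-type libraries were set beside 100 simulations of unchanged groups and 6 splits of the controls.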

Results

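The transcriptomes of mouse embryonic stem cells (ESCs), cultured pluripotent cells, were measured by RNA-seq in 12 libraries that form 3 groups of 4. Wild-type ESCs were grown in 2i medium, a serum-free medium with the GSK3 inhibitor CHIR99021 at 3 µM, the MEK inhibitor PD0325901 at 1 µM and the cytokine LIF at 1000 units/mL. ESCs labelled as knockout for Tfcp2l1, a transcription factor of the grainyhead-like family, were grown in the same medium. The other group was wild-type ESCs in medium with 15% fetal bovine serum (FBS) and LIF at 1000 units/mL. Each transcript level is an FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped in the library) that the authors deposited, summed here per gene. The number of reads behind each library is unknown. The FPKM values of a library summed to between 347772 and 358340, and 11547 to 11873 genes per library reached 1 FPKM. For transcripts between 5 and 20 FPKM, the authors' interval around a value reached a median of 8.32% to 10.0% of that value to either side, depending on the library.

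Libraries of a group resembled each other more than libraries of different groups. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.9811 to 0.9953 within groups, 0.9615 to 0.9735 between knockout and wild type in 2i, and 0.8961 to 0.9184 between wild type in 2i and in FBS. The first principal component held 68.8% of the variance and set the 4 FBS libraries apart from the 8 libraries in 2i. The second held 17.4% and set the knockout apart from wild type in 2i. On the next component, with 3.3%, wild type in 2i replicate 3 lay at -20.84 and its group's replicate 2 at 14.77. No pair of the 66 pairs of libraries held identical values.

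Genes on chromosome 6, which include Nanog, Dppa3, Gapdh and Peg10, shifted together from library to library. Their median offset from the gene means ranged from -0.169 (FBS replicate 3) to 0.226 (wild type in 2i replicate 4) on the log2 scale, a range of 0.395, against at most 0.144 for any other chromosome. Wild type in 2i held offsets of 0.065, 0.209, -0.13 and 0.226 in replicates 1 to 4, and the 4 knockout libraries lay between -0.119 and 0.011. Values of chromosome 6 genes below carry this shift: in the knockout, 75 of 579 tested chromosome 6 genes rose, 195 fell and their median log2 change was -0.145.

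**Figure D1:**
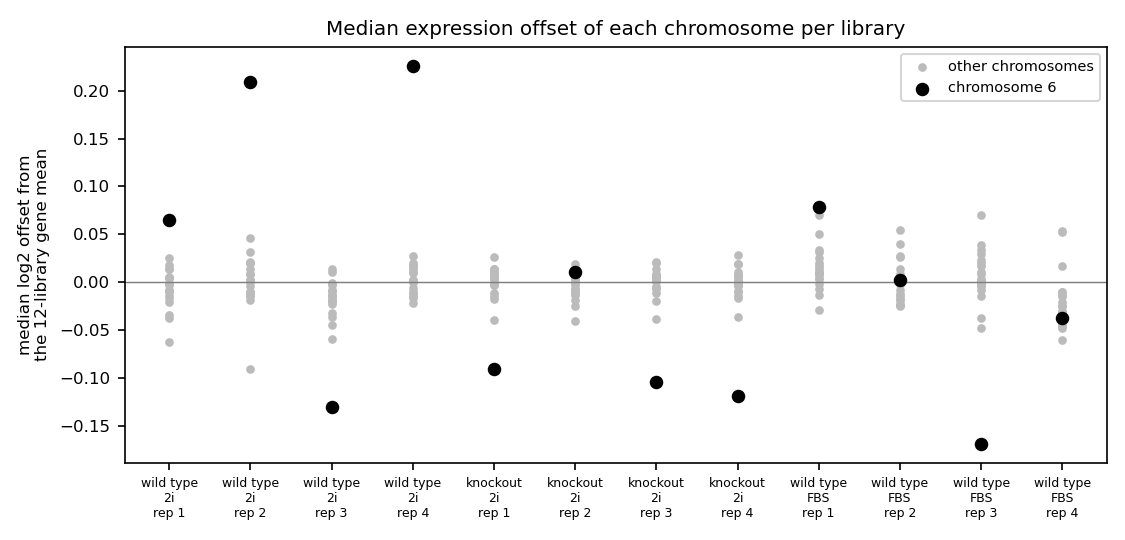
Median log2 offset of each chromosome's genes (at least 5 FPKM on average) from their 12-library mean, per library, with chromosome 6 in black and the other chromosomes in grey. Chromosome 6 spans -0.169 to 0.226, while no other chromosome spans more than 0.144.

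The first comparison set the knockout against wild type in 2i, to find the transcripts that Tfcp2l1 regulates in that medium. Tfcp2l1 itself (NM_023755; mm9, chromosome 1, 120524522 to 120581745) stood at 133.3, 143.2, 112.3 and 139.3 FPKM in the 4 wild-type libraries in 2i and at 76.1, 72, 82.9 and 84.7 FPKM in the 4 knockout libraries. The means were 132 ± 13.8 and 78.92 ± 5.92 (SD, n = 4 each), so the knockout kept 59.8% of the wild-type level. All 4 knockout values lay below all 4 wild-type values (log2 change -0.73, SE 0.10, limma adjusted p = 0.000119; exact two-sided permutation p = 0.0286, the smallest that 70 splits allow). In FBS, Tfcp2l1 stood at 25.8, 37.1, 30.7 and 31.5 FPKM. The value covers the whole transcript, so loss of single exons could not be seen, and the level of the transcript does not by itself check the knockout label.

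Expression changed widely in the knockout, mostly by small amounts. Of 12329 genes tested, 5589 (45.3%) passed an adjusted p of 0.05, 2954 higher and 2635 lower, with a median absolute log2 change of 0.35. With an absolute log2 change of at least 1 as well, 358 genes remained, 160 higher and 198 lower. The 4 knockout libraries did not overlap the 4 wild-type libraries for 5442 genes (44.1%), where chance gives 2.9%. All log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and group values are means ± SD with n = 4. With the mean level of fibroblast markers added to the model, a setting chosen after the data were seen, 1961 genes passed.

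Ppp1r14d, an inhibitory subunit of protein phosphatase 1, fell furthest on the log2(FPKM + 1) scale: from 20.1 ± 5.48 FPKM in wild type to 0.101 ± 0.0949 in the knockout (NM_028104; chromosome 2, 119043859 to 119055601; log2 change -4.23, SE 0.16, adjusted p = 4.75e-09). Ly75, an endocytic receptor, fell from 17.3 ± 0.38 to 1.41 ± 0.132 FPKM (log2 change -2.92, SE 0.07), and Mymx, a muscle fusion peptide, from 43.3 ± 4.24 to 5.20 ± 0.86 FPKM. The other genes among the 10 deepest falls were Xlr5b (9.15 to 0.355 FPKM), the homeobox gene Tlx2 (8.44 to 0.557), Vwf (6.86 to 0.375), S100a1 (38.2 to 6.11), Wfdc2 (103 to 19.8), Rerg (13.6 to 1.92) and the prostaglandin synthase Ptges (14.1 to 2.28). Tlx2, Vwf and Rerg lie on the shifting chromosome 6, and Xlr5b shares sequence with close relatives, so its reads are uncertain.

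Ct55 and Lefty1 rose furthest in the knockout on the log2(FPKM + 1) scale. Ct55, a cancer/testis gene, went from 0.804 ± 0.564 to 15.6 ± 2.52 FPKM (NM_029142; chromosome X, 51028008 to 51041399; log2 change 3.24, SE 0.19, adjusted p = 1.23e-07). Lefty1, a secreted inhibitor of Nodal, went from 1.95 ± 0.594 to 21.9 ± 2.21 FPKM (NM_010094; chromosome 1, 182865170 to 182868532; log2 change 2.98, SE 0.21, adjusted p = 5.48e-07). Klhl13, an X-linked ubiquitin ligase adaptor, rose from 20.2 ± 1.29 to 96.6 ± 4.53 FPKM, and Dppa3, a maternal factor also counted as a naive marker, from 12.3 ± 1.69 to 58.5 ± 5.27 FPKM. The remaining rises of the 10 largest were the proneural factor Neurog1 (0.477 to 7.34 FPKM), Ap3b2 (2.69 to 18.8), Foxi3 (0.482 to 6.57), Prr19 (1.07 to 8.34), the Wnt effector Lef1 (1.19 to 8.61) and Fgfbp1 (5.43 to 27.5). Dppa3 and Foxi3 are on chromosome 6 and rose against that chromosome's median of -0.145.

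**Figure D2:**
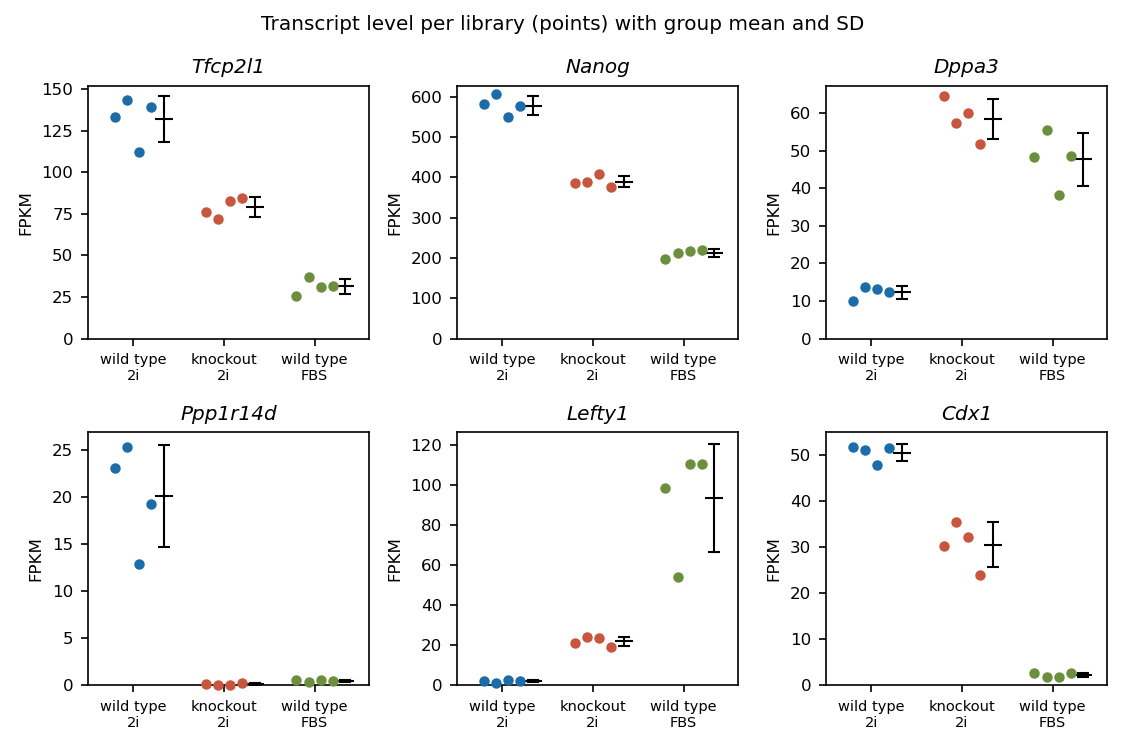
FPKM per library (points) for 6 genes in the 3 groups, with the group mean and SD (n = 4) as black bars; every vertical axis starts at 0. Tfcp2l1 and Nanog lie highest in wild type in 2i, intermediate in the knockout and lowest in FBS, while Ppp1r14d lies near 0 in the knockout and in FBS.

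Naive pluripotency genes, which mark the ground state that 2i maintains, fell as a group in the knockout. Of 20 tested, 10 fell, 2 rose and 8 did not pass; adjusted over the list alone, 11 fell and 2 rose. Nanog, on chromosome 6, fell from 578 ± 23.7 to 390 ± 14.1 FPKM (log2 change -0.57, SE 0.05), Pecam1 from 55.5 ± 3.93 to 37.1 ± 2.58 FPKM and Mras from 9.04 ± 2.6 to 2.50 ± 0.313 FPKM. Dppa3 was 1 of the 2 that rose. Fbxo15 did not pass, at 263 ± 33.6 and 279 ± 28.8 FPKM. The list was lower by limma's camera with a preset correlation (adjusted p = 0.0107), with adjusted p = 0.512 with an estimated correlation.

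Epiblast, neuroectoderm and trophoblast genes were higher as groups in the knockout. Of 19 formative and primed epiblast genes 10 rose and 3 fell, with Cldn6 at 5.69 ± 0.495 and 16.8 ± 1.14 FPKM, Lin28b at 0.727 ± 0.159 and 2.18 ± 0.245 FPKM, and the ETS factor Etv4 falling from 13.1 ± 4 to 2.99 ± 0.593 FPKM. Of 9 neuroectoderm genes 7 rose, among them Sox11 (2.12 to 4.27 FPKM) and the filament gene Nes (1.69 to 3.57), and the RNA-binding Msi1 alone fell (21.4 to 10.9). Of 15 trophoblast genes 8 rose and 2 fell, with the transcription factors Cdx2 (0.666 ± 0.0682 to 3.54 ± 0.428 FPKM) and Gata3 (0.742 to 2.44) and the receptor Fgfr2 (0.391 to 1.75) among the rises. The camera adjusted p was 0.0409, 0.0288 and 0.0178 for the 3 lists, and adjusted p = 0.512, 0.446 and 0.512 with an estimated correlation. The epiblast call was lost without wild type in 2i replicate 2 (adjusted p = 0.0548) or replicate 4 (0.0538), and the trophoblast call without replicate 3 of that group (0.0526). With the filter raised to 5 FPKM the 3 lists gave adjusted p = 0.26, 0.392 and 0.26; after quantile normalization the epiblast and neuroectoderm lists gave 0.0741 and 0.06. The epiblast call was also lost as TPM (0.0521), with the 8 libraries alone (0.0583), with the replicate block (0.056) and by ranks (0.0613). It was lost as well without chromosome 6 genes (0.0553) or their offset (0.0515). The neuroectoderm call was lost with the highest entry per symbol (0.0509) and the trophoblast call with no filter (0.0665).

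Transcripts of the 2-cell-like state, a rare ESC state that shares transcripts with the early embryo, were higher: 9 of 12 tested rose and none fell, and adjusted over the list alone 11 rose. Zscan4b went from 21.4 ± 12.9 to 52.8 ± 14.2 FPKM, Tmem92 from 22.8 ± 11.2 to 48.8 ± 9.9 and Usp17le from 8.47 ± 4.05 to 19.3 ± 5.11. Zscan4f did not pass, at 64.3 ± 38.2 and 130 ± 33.2 FPKM (adjusted p = 0.0574). It did pass after quantile normalization (0.0443), with the 8 libraries alone (0.0455), with the replicate block (0.0334) and with array weights (0.0294). Leaving out wild type in 2i replicate 1 (0.0408) or 3 (0.0229) or knockout replicate 4 (0.0479) also gave it a call. For the list, the camera adjusted p was 0.00852, and adjusted p = 0.547 with an estimated correlation, which was 0.91 among the members. Members share reads with near-identical copies and varied widely within wild type; Tmem92, Zscan4b and Usp17le did not pass with a pseudocount of 0.1 (adjusted p = 0.0587, 0.0623 and 0.0685), and the list did not pass with 0.01 (0.0768).

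Wnt and beta-catenin targets were higher, with 10 of 17 up and 1 down (adjusted p = 0.00947; adjusted p = 0.512 with an estimated correlation). Lef1 and Cdx2 were among them, as was the ligand Wnt8a, from 0.02 ± 0.0137 to 2.01 ± 0.466 FPKM. The member that fell was the homeobox gene Cdx1, from 50.5 ± 1.86 to 30.5 ± 4.86 FPKM. Among 22 imprinted genes, which are expressed from 1 parental allele, 10 rose and 2 fell (adjusted p = 0.0288; adjusted p = 0.512 with an estimated correlation), and 11 rose and 2 fell adjusted over the list alone. Peg3 rose from 24.2 ± 6.08 to 55.2 ± 9.92 FPKM, Snrpn from 45.0 ± 2.43 to 65.1 ± 1.88 and Ndn from 5.29 ± 0.988 to 10.3 ± 0.448. The imprinted call was lost without wild type in 2i replicate 3 (adjusted p = 0.0508), and without chromosome 6 genes (0.0649) or after quantile normalization (0.0518). The Wnt call was lost with a filter of 5 FPKM (0.178).

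Actin cytoskeleton and serum-response genes were higher in the knockout, with 18 of 29 up and 2 down (19 and 3 adjusted over the list alone; camera adjusted p = 0.00852; adjusted p = 0.512 with an estimated correlation). The galectin Lgals1 rose from 79.9 ± 12.3 to 145 ± 16.3 FPKM, the annexin Anxa3 from 2.53 ± 0.772 to 7.37 ± 1.18 and the tropomyosin Tpm1 from 49.8 ± 5.13 to 79.6 ± 8.69. Actb did not pass, at 1051 ± 102 and 1155 ± 51.5 FPKM. Markers of fibroblasts moved the same way: 19 of 20 rose (adjusted p = 3.88e-06; adjusted p = 0.353 with an estimated correlation), with Col1a1 at 69.5, 131 and 25.4 FPKM in wild type in 2i, knockout and FBS, and Dcn at 9.84, 19.5 and 0.523 FPKM. Their mean log2 level was 3.26 ± 0.25 in wild type in 2i, 3.98 ± 0.29 in the knockout and 2.76 ± 0.13 in FBS. With that level in the model, adjusted p was 0.509 for actin, 0.101 for naive, 0.109 for epiblast, 0.154 for neuroectoderm, 0.0517 for Wnt, 0.165 for imprinted, 0.316 for cholesterol, 0.165 for glycolysis and 0.0517 for respiratory chain genes. The trophoblast, 2-cell-like and lysosome lists passed. Lgals1, Anxa3 and Tpm1, and Mras, Nes, Cdx1, Pfkp, Aldoa, Gapdh, Insig1, Dnmt3l, Dnmt3a and Uhrf1, then had adjusted p from 0.0546 (Lgals1) to 0.285 (Nes). Their directions were kept, and the log2 change went from -0.48 to -0.54 for Aldoa, -0.39 to -0.39 for Uhrf1, 0.89 to 0.83 for Dnmt3a and 1.00 to 0.83 for Dnmt3l, but from 1.26 to 0.53 for Anxa3, 0.86 to 0.45 for Lgals1 and 0.77 to 0.37 for Nes. The median SE of the genes called without the covariate went from 0.08 to 0.13.

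**Figure D3:**
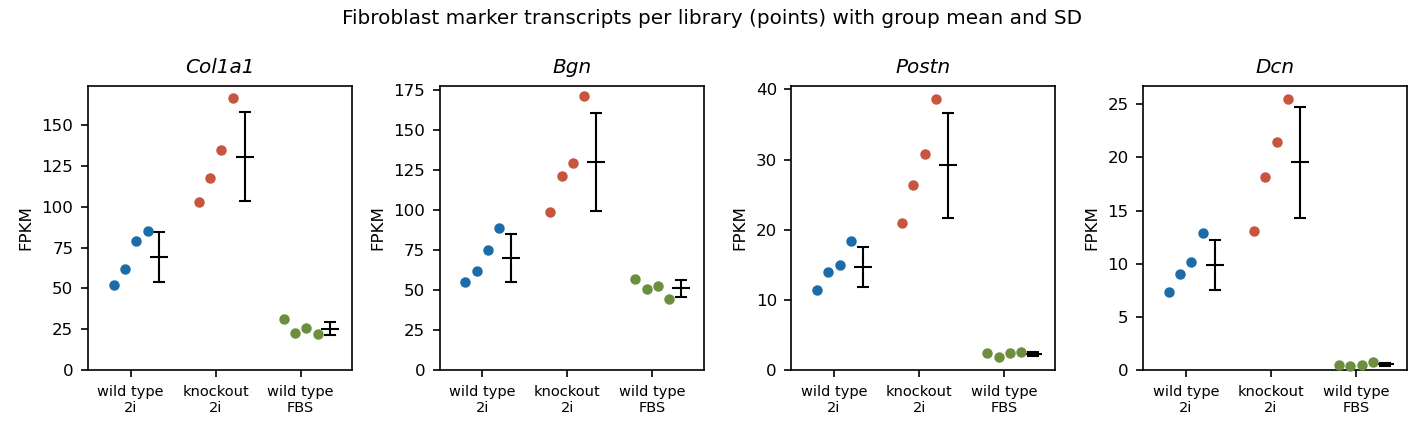
FPKM per library (points) of 4 fibroblast markers in the 3 groups, with the group mean and SD (n = 4) as black bars; every vertical axis starts at 0. Mean Col1a1 stands at 69.5 FPKM in wild type in 2i, 131 in the knockout and 25.4 in FBS.

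Cholesterol synthesis, glycolysis, respiratory chain and lysosome genes were lower in the knockout. Of 25 cholesterol synthesis genes 12 fell and none rose (14 fell adjusted over the list alone), among them Insig1 (76.6 ± 10.9 to 51.9 ± 3.19 FPKM). Of 21 glycolysis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone), including Hk1 (34.4 to 20.5 FPKM), Pfkp (94.3 to 68.0) and Aldoa (933 to 667). Gapdh, on chromosome 6, fell from 817 ± 64.6 to 678 ± 32.5 FPKM but did not pass after quantile normalization (adjusted p = 0.0862). Of 27 respiratory chain genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with Ndufb8 at 220 ± 5.77 and 159 ± 2.88 FPKM and Cox6c at 257 ± 13.2 and 186 ± 5.35. Of 26 lysosome and autophagy genes 10 fell and 2 rose, led by Tfeb, a master regulator of lysosomal genes (14.8 ± 1.52 to 5.57 ± 0.491 FPKM), and Lamp1 (175 to 140). The camera adjusted p was 0.000571, 0.00852, 0.000571 and 0.0288 in that order, and adjusted p = 0.541, 0.547, 0.446 and 0.582 with an estimated correlation. The lysosome call was lost without wild type in 2i replicate 4 (adjusted p = 0.0994), with a filter of 5 FPKM (0.0611), after quantile normalization (0.0706) and without chromosome 6 genes (0.053).

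The other 12 of the 24 lists were not called in the knockout, though single members changed strongly. LIF and STAT3 targets (6 up and 5 down of 18; adjusted p = 0.98) held Icam1, which fell from 45.2 ± 5.97 to 14.5 ± 1.11 FPKM, and Stat3, from 23.3 ± 3.52 to 14.3 ± 0.678. Junction and epithelial genes (5 up and 8 down of 25; 0.363) held the protease inhibitor Spint1 (60.1 ± 14.6 to 13.1 ± 1.16 FPKM), its target protease St14 (39.2 to 11.2) and E-cadherin, Cdh1 (121 ± 11 to 71.8 ± 4.71). BMP and Nodal targets (8 up and 4 down of 17; 0.283) held Lefty1, Id1 (11.3 to 25.1 FPKM) and Smad7 (26.4 to 9.98). ERK targets (14 up and 3 down of 23; 0.0514) held Spry2 (80 to 135 FPKM) and Dusp6 (15.6 to 26.6), and the list passed without wild type in 2i replicate 2 (0.0361) or knockout replicate 1, 3 or 4 (0.0418, 0.0367 and 0.0469). The ERK list also passed with median-ratio scaling (0.0479) and with rank-based camera (0.0459). DNA methylation genes (5 up and 3 down of 14; 0.98) held Dnmt3l (33.1 to 64.4 FPKM), Dnmt3a (6.15 to 12.1) and Uhrf1 (107 to 80.7). Germline genes (6 up and 7 down of 18; 0.334) held Dpep3 (7.71 to 2.11 FPKM), Tuba3a on chromosome 6 (82.3 to 32.6) and Mael (4.97 to 10.3). Counts up and down were 5 and 2 of 14 for general pluripotency (0.283), 4 and 2 of 16 for endoderm (0.334), 5 and 3 of 9 for streak and mesoderm (0.525), 6 and 2 of 20 for p53 targets (0.463), 4 and 7 of 20 for stress responses (0.278) and 4 and 7 of 25 for the cell cycle (0.209). Adjusted over the list alone, LIF targets had 7 up, junction genes 6 up, and the other lists not called had the same counts. The germline list had a median log2 change of 0.05, a mean of -0.34 and a downward test; the methylation list a median of -0.03, a mean of 0.1 and an upward test.

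**Figure D4:**
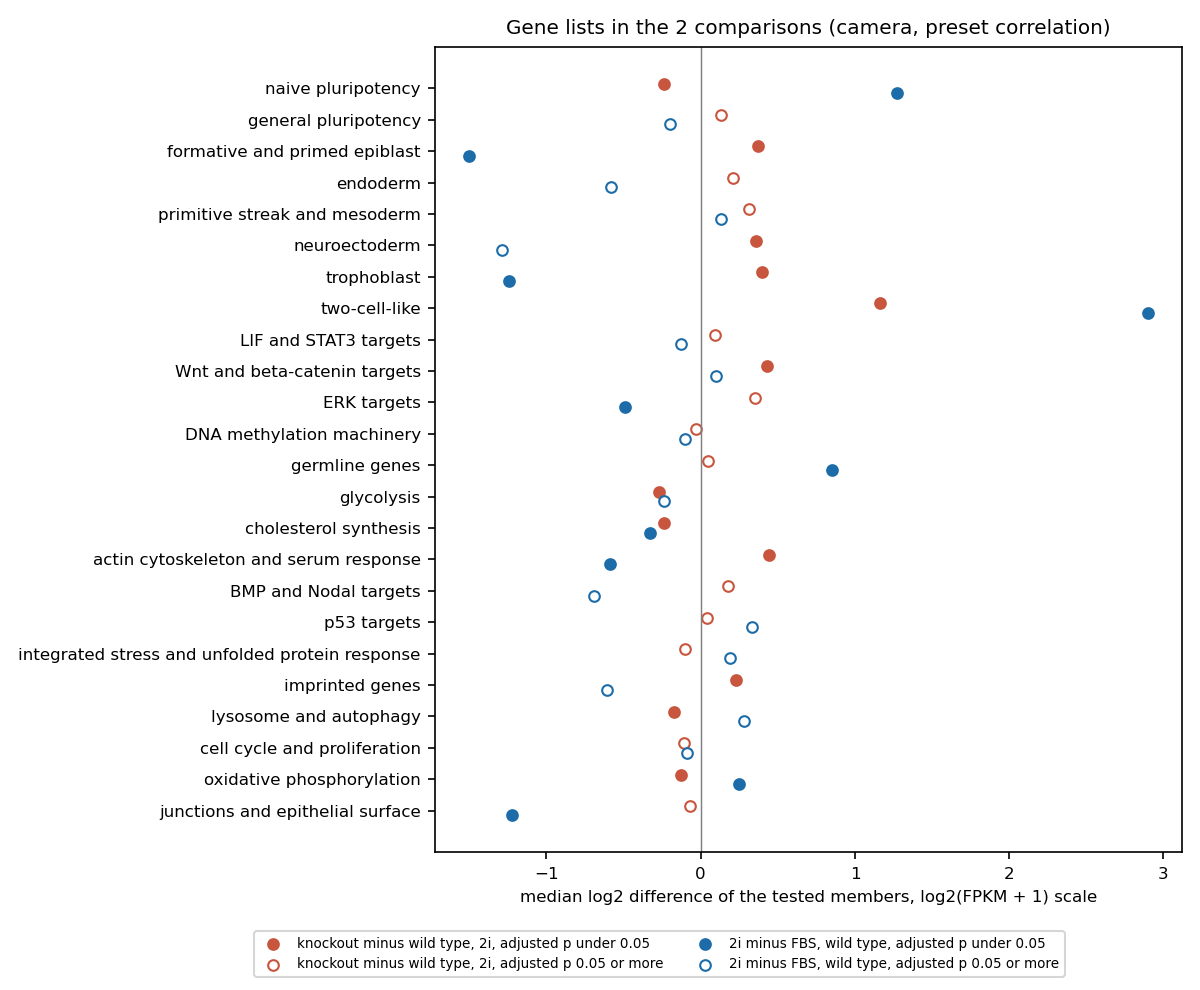
Median log2 difference of the tested members of each of 24 gene lists, knockout minus wild type in 2i (red) and 2i minus FBS in wild type (blue); filled points have a camera adjusted p under 0.05 with a preset correlation. Naive genes lie at -0.24 in the knockout and at 1.27 in 2i against FBS, and 2-cell-like genes lie above 0 in both, at 1.16 and 2.9.

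The second comparison set wild-type ESCs in 2i against wild-type ESCs in FBS, which the series' design names for a gene set analysis. Of 12329 genes tested, 8928 (72.4%) differed, 4579 higher in 2i and 4349 lower, with a median absolute log2 difference of 0.492. With an absolute log2 difference of at least 1 as well, 1563 differed, 874 higher in 2i and 689 lower. For 7703 genes (62.5%) the groups did not overlap, where chance gives 2.9%. Tfcp2l1 in FBS stood at 23.7% of its level in 2i (log2 difference 2.05, SE 0.10, adjusted p = 3.09e-09).

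Zscan4f, a marker of the 2-cell-like state, and Cdx1 had the largest differences above FBS on the log2(FPKM + 1) scale; by the ratio of FPKM alone, lower genes such as Tmem92 and Ppp1r14d stood further above FBS. Zscan4f stood at 64.3 ± 38.2 FPKM in 2i and 2.88 ± 2 in FBS (NM_001110316; chromosome 7, 11983264 to 11987667; log2 difference 4.04, SE 0.47, adjusted p = 5.87e-06), with reads shared among its copies. Cdx1, a Wnt-responsive homeobox gene, stood at 50.5 ± 1.86 and 2.18 ± 0.469 FPKM (NM_009880; chromosome 18, 61178516 to 61195853; log2 difference 4.03, SE 0.12, adjusted p = 6.49e-11). The rest of the 10 largest were Tmem92 (22.8 and 0.445 FPKM), Elobl (50.2 and 2.54), Ppp1r14d (20.1 and 0.450), Fkbp6 (32.6 and 1.44), Xlr3c (23.1 and 0.659), Tuba3a (82.3 and 5.18), Obox6 (26.3 and 1.07) and the germ cell RNA-binding gene Dazl (40.6 and 2.20). Xlr3c and Obox6 belong to families of close copies.

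Car4, a carbonic anhydrase, was the gene furthest below its FBS level on that scale, at 0.0258 ± 0.0333 FPKM in 2i and 32.9 ± 6.57 in FBS (NM_007607; chromosome 11, 84771256 to 84779556; log2 difference -5.02, SE 0.15, adjusted p = 7.94e-11). Lefty1 stood at 1.95 ± 0.594 and 93.7 ± 26.8 FPKM (log2 difference -4.97, SE 0.21) and the imprinted gene Peg10, on chromosome 6, at 15.0 ± 6.86 and 370 ± 51.1. The splicing regulator Esrp1 (0.197 and 25.6 FPKM), S100a4 (1.20 and 47.6), Rhox9 (1.16 and 46.7), Crmp1 (0.5 and 30.9), the iron exporter Slc40a1 (0.146 and 21.8), the ligand Wnt7b (0.371 and 22) and Plac8 (0.681 and 26) followed.

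Naive pluripotency genes were higher in 2i, with 19 of 20 higher and 1, Dppa3, lower (12.3 ± 1.69 FPKM in 2i, 47.7 ± 7.14 in FBS; named after its values were seen). Nanog stood at 578 ± 23.7 and 212 ± 10.2 FPKM, Tbx3 at 94.0 ± 1.49 and 17.5 ± 3.59, the junction gene Jam2 at 58.4 ± 3.97 and 8.74 ± 1.39, and Zfp42 (Rex1) at 55.0 ± 1.35 and 29.8 ± 1.59. All 12 tested 2-cell-like genes were higher, such as Zscan4a at 28.1 ± 16.8 and 1.15 ± 0.816 FPKM. Germline genes were higher for 16 of 18 and lower for none, with Tuba3a, the dipeptidase Dpep3 (7.71 ± 1.46 and 0.271 ± 0.0995 FPKM) and the meiotic axis gene Hormad1 (11.5 ± 1.95 and 1.20 ± 0.397). Of 27 respiratory chain genes 19 were higher and 2 lower, with Cox5a at 526 ± 19 and 262 ± 6.1 FPKM and Ndufb8 at 220 ± 5.77 and 132 ± 5.15. Camera gave adjusted p = 8.52e-06, 0.000335, 5.02e-05 and 0.00399 for the 4 lists, and adjusted p = 0.372, 0.44, 0.395 and 0.395 with an estimated correlation.

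Epiblast, trophoblast and epithelial genes were lower in 2i. Of 19 formative and primed epiblast genes 14 were lower and 4 higher, with the methyltransferase Dnmt3b at 10.0 ± 2.59 FPKM in 2i and 103 ± 17.8 in FBS, Cldn6 at 5.69 and 84.1, Lin28b at 0.727 and 5.30 and the POU factor Pou3f1 at 2.48 and 12.2. Of 15 trophoblast genes 14 were lower and 1 higher, with Hand1 (0.209 ± 0.0632 and 12.3 ± 1.92 FPKM), Fgfr2 (0.391 and 11.5) and the keratin Krt18 (7.53 ± 3 and 127 ± 23.9). Of 25 junction and epithelial genes 19 were lower and 4 higher, with Epcam (40.2 ± 3.27 and 136 ± 10.3 FPKM), Esrp1 and the trafficking GTPase Rab25 (0.537 ± 0.234 and 13.2 ± 2.84). The camera adjusted p was 0.00386, 4.46e-05 and 5.02e-05, and adjusted p = 0.395, 0.372 and 0.395 with an estimated correlation. With a filter of 5 FPKM the epiblast list gave 0.0534.

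ERK targets, which the MEK inhibitor of 2i acts on, were lower in 2i for 14 of 23 and higher for 4: the phosphatases Dusp6 (15.6 ± 0.864 FPKM in 2i and 44.3 ± 4.97 in FBS) and Dusp4 (4.44 ± 0.152 and 16.9 ± 3.85) and the feedback inhibitor Spry4 (2.34 ± 0.984 and 18.3 ± 3.29). Ier2 did not pass, at 125 ± 13.2 and 113 ± 4.72 FPKM. Cholesterol synthesis genes were lower for 15 of 25 and higher for 3, with Idi1 at 20.1 ± 1.9 and 41.6 ± 1.93 FPKM, Sqle at 25.2 ± 1.3 and 41.9 ± 1.46, and Tm7sf2 higher at 12.9 ± 2.16 and 5.87 ± 0.48. Actin and serum-response genes were lower for 18 of 29 and higher for 5 (19 and 5 adjusted over the list alone), with S100a6 at 19.2 ± 4.02 and 153 ± 25 FPKM, Lgals1 at 79.9 and 269, the calponin Cnn1 at 0.395 and 3.99, and its relative Cnn3 higher in 2i at 392 ± 26.4 and 159 ± 10. Of 20 fibroblast markers 11 were higher in 2i and 4 lower (adjusted p = 0.0899; adjusted p = 0.655 with an estimated correlation). The camera adjusted p was 0.0249, 0.0287 and 0.00629 for ERK, cholesterol and actin, and adjusted p = 0.395, 0.559 and 0.423 with an estimated correlation. The cholesterol call was lost without wild type in 2i replicate 3 (adjusted p = 0.0638) or FBS replicate 4 (0.0505), with a filter of 5 FPKM (0.0601) and with the fibroblast marker level in the model (0.161). The ERK call was lost with that filter (0.0534).

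The remaining 14 lists were not called between the media. Wnt and beta-catenin targets, which CHIR99021 acts on, split into 8 higher and 7 lower in 2i of 17 (adjusted p = 0.721): Axin2 (13.3 ± 1.73 FPKM in 2i and 2.53 ± 0.654 in FBS), Sp5 (10.3 ± 3.7 and 0.621 ± 0.252) and Cdx1 were higher, and Bmp4 (1.41 ± 0.358 and 12.4 ± 2.91) was lower. Imprinted genes (4 higher and 13 lower of 22; 0.0637) held Nnat (1.31 ± 0.153 and 25.5 ± 2.97 FPKM) and Peg10 below FBS and Plagl1 above it (33.9 ± 3.87 and 3.10 ± 0.586). Glycolysis genes (4 and 11 of 21; 0.0551) held Pkm (576 ± 16.3 and 1049 ± 28.7 FPKM) and Ldha (239 ± 35 and 553 ± 37.9). General pluripotency genes (3 and 7 of 14; 0.0601) held Utf1 (60.7 ± 3.9 and 383 ± 16.8 FPKM) and Lin28a (12.8 ± 4.18 and 113 ± 16.7). DNA methylation genes (5 and 7 of 14; 0.338) held Dnmt3l (33.1 ± 11.5 and 301 ± 33.5 FPKM) below FBS and Tet2 (19 ± 1.26 and 8.08 ± 0.386) above it. LIF and STAT3 targets (7 and 7 of 18; 0.946) held Klf4 (264 ± 63.8 and 91.9 ± 11.5 FPKM) and Mycn (25.7 ± 1.8 and 97.6 ± 6.59). Counts higher and lower were 3 and 10 of 16 for endoderm (0.061), 2 and 3 of 9 for streak and mesoderm (0.986), 3 and 6 of 9 for neuroectoderm (0.202), 7 and 9 of 17 for BMP and Nodal targets (0.572), 13 and 4 of 20 for p53 targets (0.0997), 10 and 3 of 20 for stress responses (0.0917), 13 and 4 of 26 for lysosome and autophagy (0.0637) and 10 and 9 of 25 for the cell cycle (0.614). Adjusted over the list alone, LIF targets had 8 lower and p53 targets 5 lower, and the counts of the other lists not given above were the same. Leaving out 1 library gave some of these lists a call: glycolysis without wild type in 2i replicate 1 (0.0477), 2 (0.029) or 4 (0.0427) or FBS replicate 1 (0.0461) or 2 (0.0458); general pluripotency without wild type in 2i replicate 1 (0.0477) or 3 (0.0333) or FBS replicate 1 (0.0363); endoderm (0.0483) and imprinted genes (0.0427) without wild type in 2i replicate 4; p53 targets (0.0477) without replicate 1 and lysosome genes (0.0333) without replicate 3 of that group. The streak and mesoderm list had a median of 0.13, a mean of 0.05 and a downward test.

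Markers of other cell types were measured alongside. In the knockout, the counts up and down were 4 and 1 of 10 for parietal and visceral endoderm (adjusted p = 0.163; 6 and 1 adjusted over the list alone), 4 and 0 of 8 for epiblast-like cells (0.151), 3 and 1 of 6 for trophoblast-like cells (0.146) and 2 and 0 of 2 for neural-like cells (0.146). Between 2i and FBS, the counts higher and lower in 2i were 1 and 6 of 10 (0.0899), 1 and 6 of 8 (0.0308), 0 and 6 of 6 (0.01) and 0 and 2 of 2 (0.0899) in the same order; the epiblast-like and trophoblast-like lists gave adjusted p = 0.288 and 0.0572 with an estimated correlation. The Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty summed to at most 1.34 FPKM in any library, and Xist stood at 0.515, 1.05 and 0.918 FPKM in wild type in 2i, knockout and FBS.

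The differences of the knockout and of FBS from wild type in 2i, called effects here, were set against each other gene by gene. Of the 358 genes that changed in the knockout by an absolute log2 of at least 1, 269 also changed in FBS in the same direction, among them Ppp1r14d, Ly75, Lefty1, Klhl13 and Lef1. Another 51 changed the opposite way, such as Etv4, which stood at 13.1 FPKM in wild type in 2i, 2.99 in the knockout and 31.2 in FBS, and Tmem92, at 22.8, 48.8 and 0.445 FPKM. The other 38 did not pass in FBS, among them Tfeb (14.8, 5.57 and 13.9 FPKM). Both comparisons share the 4 wild-type libraries in 2i, which by itself makes their effects alike. Across genes, Pearson's r of the 2 effects was 0.452 and Spearman's rho 0.485, while simulated unchanged groups against the same controls gave a mean r of 0.504. That r is fixed by the design of the simulation, in which no gene changed. With many changed genes, as here, it is no baseline for r, nor is the simulated share of same signs below. The covariance can be compared. The covariance was 0.135 against a simulated mean of 0.0061 (highest 0.0088), a difference of 0.1289. Of the called genes, 1845 were higher in both (1042 for independent lists), 1874 lower in both (979) and 725 went opposite ways (2027); 68.6% of tested genes had the same sign, against 66.7% simulated. With the controls split so that each effect had its own 2 libraries, 6 ways gave a Pearson's r of 0.316 to 0.488 and a covariance of 0.1052 to 0.1422. In these splits 1250 to 1576 genes were higher in both (641 to 896 for independent lists) and 1304 to 1572 lower in both (600 to 839). Opposite ways went 378 to 737 genes (1247 to 1732). Etv4, Tmem92 and Tfeb were picked as examples after their values were seen.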

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

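The copy number, Tfcp2l1 loss, both fibroblast and wild-type cell tests were chosen only after the results were seen.

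Chromosome 6 genes shifted together from library to library, over a log2 range of 0.395. After a trend with GC content and transcript length was removed, the range was still 0.365 (0.393 before, over the genes with a GC value, 98.5%), above the 0.144 that no other chromosome exceeded, which argues against that bias. Loss of Tfcp2l1 cannot shift wild-type libraries, yet they ranged over 0.356 in 2i and 0.248 in FBS, against at most 0.091 within a group for any other chromosome (0.161 and 0.116 with the library left out that narrows each most). Whether it adds to the knockout mean, -0.169 from wild type in 2i, cannot be told apart from these shifts: the exact permutation p was 0.1429, and 3 of 4 wild-type libraries in 2i lay above all 4 of the knockout. All 15 of the 15 bins of 10 Mb varied by more than any other whole chromosome. That count decides little, because bins of 6 to 57 genes vary more by noise than whole chromosomes, and bins of other chromosomes were not measured. The lowest correlation of a bin with the rest was 0.42. A copy number change of the chromosome in part of the cells may account for the shared shift, as a hypothesis, since DNA was not measured here.

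Fibroblast markers were higher in the knockout, with a median ratio to wild type of 1.84 (0.92 for Pdgfrb to 2.34). The sum of 4 Y-linked transcripts was 2.19 times that of wild type (exact permutation p = 0.0286, the smallest that 4 against 4 can give), at 0.318 to 0.558 FPKM in wild type in 2i and 0.586 to 1.34 in the knockout. In FBS it was 0.329 to 0.699 FPKM, 1.23 times wild type in 2i (exact permutation p = 0.3429), although the marker level was lower there by a log2 difference of -0.5, which goes against that sum as a measure of feeder RNA across media. Over the 12 libraries, centred by group, the marker level and this sum gave Pearson's r of 0.76 (permutation p = 0.0104) and Spearman's rho of 0.75 (p = 0.0146); without the 2 libraries farthest from the median r was 0.59 over 10 libraries and its permutation p 0.107. RNA from feeder fibroblasts and higher expression by the knockout stem cells may each account for the markers and cannot be told apart. The sum moved with the markers within groups, but between the media it did not: in FBS the mean marker level was lower and the sum was not. The markers did not move alike there: of 20, 11 were lower in FBS and 4 higher, such as S100a4 (1.2 FPKM in wild type in 2i and 47.6 in FBS).

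Tfcp2l1 stood at 59.8% of wild type in the knockout. Wild-type cells in the knockout cultures could leave such a level only if other transcripts stayed above a like share, yet 52 of 8215 genes at 5 FPKM or more in wild type lay below 29.9% in all 4 knockout libraries, 7 of them below 10%, and Ppp1r14d at 0.5%. That argues against wild-type cells as the whole cause. A transcript still made from the disrupted gene cannot be told apart from other causes, because exons were not measured separately.

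Among 429 groups of 4 libraries checked, 17 held a library far from its others; chance gives about 1 in 20. In the knockout, Tpm1 stood at 92.5 FPKM in replicate 2 (others 73.9 to 76.5), Krt19 at 1.02 in replicate 2 (0.594 to 0.666), Rab25 at 0.494 in replicate 3 (0.583 to 0.592), and in replicate 4 Ct55 at 11.8 (16.7 to 17.2), Pou3f1 at 2.42 (2.1 to 2.15) and H4c9 at 16 (23.7 to 25). In wild type in 2i, Dazl stood at 71.8 FPKM in replicate 3 (26.1 to 33.6), and in replicate 4 Jam2 at 52.5 (60 to 61.1), Epcam at 45.1 (38.4 to 38.8) and Rab25 at 0.888 (0.4 to 0.437). In FBS, Plac8 stood at 16.5 FPKM in replicate 2 (28.1 to 30.3), Neurog1 at 3.02 in replicate 4 (0.949 to 1.08), and in replicate 3 Xlr5b at 1.22 (0.0633 to 0.257), S100a1 at 11.3 (5.82 to 6.49) and Xlr3a at 9.17 (0.784 to 2.17). Genes at 1 FPKM or more numbered 11785 in knockout replicate 1 (11864 to 11873). The median distance to the authors' bounds was 8.38% in wild type in 2i replicate 2 (9.89% to 9.95%).

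Each comparison was refitted on its 8 libraries under all 35 splits into 4 and 4. For genes, only 1 split, the real one, reached 5758 genes in the knockout and 8421 in FBS. The highest other split gave 1 in each. That decides little about chance, because splits that mix the groups carry the group difference in their error, which keeps their counts low. For lists, chance was not excluded: 3 splits reached the 11 lists of the knockout and 7 the 11 of FBS. The highest other split gave 12 in each. Unevenly mixed splits keep part of the real difference, so these counts are not free of it.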

How the results depend on the processing

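The chromosome 6 settings and the fibroblast covariate were chosen after the data were seen. No direction reversed. Of 1950 values of 82 genes named in the knockout comparison, 1918 kept direction and call, 24 lost the call and 8 gained it; of 1603 for 67 genes in FBS, 1599 kept it and 4 (Ier2) gained it. Of 648 list values each, 591 kept the call, 46 lost it and 11 gained it in the knockout, and 594, 16 and 38 in FBS. The cause was not tested for any of these unless stated.

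Called genes numbered 358 in the knockout and 1563 in FBS with an absolute log2 of at least 1. With the fibroblast covariate 1961 passed in the knockout, 828 higher and 1133 lower, against 2954 and 2635 without it. The higher share of the calls thus went from 52.9% to 42.2%. Of the 1961, 1878 were also called without the covariate. For the genes called without it, the median SE rose from 0.08 to 0.13 and the median absolute log2 went from 0.35 to 0.32. Why calls ended was not tested. Lists called in the knockout numbered 7 with a filter of 5 FPKM, 3 with the covariate and 0 with an estimated correlation; in FBS 16 with no filter, 0 with an estimated correlation and 22 by fry. The covariance of both effects was 0.25 and 0.307 with pseudocounts of 0.1 and 0.01, 0.09 with no filter, 0.192 as TPM, 0.109 with the covariate, and 0.118 and 0.105 with the controls split in 2 of the 6 ways. As TPM, 58.6% of genes called in the knockout were higher, against 52.9%.

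Leaving out 1 library gave 4710 to 5922 genes in the knockout and 8506 to 8966 in FBS, 10 to 13 and 9 to 13 lists, a Tfcp2l1 change of -0.81 to -0.69 and a covariance of 0.131 to 0.143. With the replicate block, 5567 and 8899 genes and 11 and 10 lists passed, and Tfcp2l1 was at -0.73; the epiblast list of the knockout did not pass (adjusted p = 0.056). The numbers did not meet the rule for pairing, that every pair correlates above 0.1: 5 of 12 pairs did, among them 3 of 4 between the 2i groups (0.06, 0.26, 0.22 and 0.19). As a hint from the data, a library correlated best with its own number in 13 of 24 comparisons, and the fibroblast marker level ranked the libraries alike in both 2i groups (2.99, 3.11, 3.4 and 3.53 against 3.66, 3.86, 4.05 and 4.33), so a shared handling remains open. Depth is unknown, so its limit on low genes could not be given.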

Other observations

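All groups and genes here were chosen after their values were seen, and members of these families share reads, so single members are uncertain.

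Replication-dependent histone genes were higher in the knockout: 36 of 46 tested rose and none fell, with a median log2 change of 0.6, or 0.6, 0.56 and 0.8 under median-ratio, quantile and TPM scaling. H3c3 rose from 11.9 to 22.7 FPKM and H4c9 from 10.2 to 22.4; with the fibroblast covariate 24 rose, the median was higher, at 0.89, and H3c3 did not pass at a log2 change of 1.20 (0.89 without it; adjusted p = 0.0522). Between 2i and FBS 7 were higher and 6 lower. The X-linked Xlr3, Xlr4 and Xlr5 genes fell in the knockout, 9 of 9 (median -2.26, or -2.26, -2.28 and -2.41), and all 9 were higher in 2i than in FBS (median 2.76). Xlr3a stood at 25.4 FPKM in wild type in 2i, 4.52 in the knockout and 3.41 in FBS. The Xlr family by symbol held 10 tested genes, of which only the 9 above were called with a fall of at least 2-fold. Over 392 symbol families and 1568 tests, these falls, 9 of 10, had adjusted p = 9.16e-13 by Fisher's exact test, which treats members that share reads as separate genes.

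Pramel genes, a family of early embryo and germ cells, rose in the knockout for 11 of 18 and fell for 3, and were higher in 2i for 16 of 18. Pramel20 stood at 21.6 FPKM in wild type in 2i, 56.0 in the knockout and 0.747 in FBS, while Pramel30 fell from 5.37 to 0.65 in the knockout. Keratins were lower in 2i for 6 of 6 (median -3.16; family adjusted p = 1.17e-05), with Krt8 at 4.13 FPKM in 2i and 64.1 in FBS and Krt19 at 0.912 and 23.5. Some genes changed in the knockout without a call in FBS: Ankrd35 went from 5.71 to 0.605 FPKM (6.09 in FBS, adjusted p = 0.265 against 2i) and the growth factor Mdk from 139 to 437 (121 in FBS, 0.144). The claudin Cldn4 fell from 86.6 to 28.3 FPKM in the knockout and stood at 193 in FBS.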
